A study of Homo sapiens with 27 samples.

How the data were processed

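Total RNA from coronary plaque of 27 patients (14 ACS, 13 sCAD) was extracted with TRIzol, and libraries were made from about 5 ng with the SMART-Seq Stranded Kit, per the labels' protocols. Trim Galore, STAR, HTSeq and Cuffdiff and the genome build GRCh38 (hg38) are named in the submitters' processing notes; their versions, the gene annotation and the strand setting of the counting are not given in the sources used here. The authors deposited one table of whole-number counts per Ensembl gene, with one column per library. It held 36603 rows; 2 identifiers stood 2 times with identical values and were used once, leaving 36601. A symbol was found for 36366 identifiers and a position in GENCODE 29 (GRCh38) for 34616. For privacy, 103 genes (Y chromosome, XIST and TSIX) were left out of all tests and tables.

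From these counts CPM values were computed with TMM factors of edgeR 4.0.16 (R 4.3.3), except in the strand measures, which used CPM of the total count. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, leaving 17828. The main test was edgeR's robust quasi-likelihood F-test of ACS against sCAD with no covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05; the common dispersion was 1.18. Standard errors were derived from the F statistic. Fold changes are ACS minus sCAD on the log2 scale. The median log2 fold change of all tested genes was 0.21 with TMM, 0.53 with RLE size factors and 0.40 with library size alone, so a fold change is relative to these shifts.

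Before the data were examined, 59 gene lists, a panel of 36 genes, the tests and the rule for naming genes were fixed. The rule took the 14 genes with the smallest p in each direction among those past the threshold, filled a direction with fewer than 14 to 8 genes with the smallest unadjusted p, required group medians of CPM in the same direction, and left out clone, LOC, LINC, antisense, pseudogene, histone and ribosomal protein names; it added the panel, and the leading members of any list that passed. A list's score was the mean log2 CPM (prior count 2) of its members, tested by a two-sided permutation test with 100000 resamples over the 58 lists with at least 5 measured members. The variance share was tested with 10000 permutations and library measures with 100000. Alternatives were RLE factors, library size alone, other filters, DESeq2 1.42.0, limma 3.58.1 voom with quality weights, covariates, subsets of libraries and each library left out.

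The scripts were tested on simulated data for ACS against sCAD, with 200 genes changed and 13831 genes tested after the filter. edgeR recovered 0 of 40 genes changed 2-fold, 9 of 40 changed 4-fold, 27 of 30 changed 8-fold and 34 of 34 changed 16-fold, with 0 false calls among 70; the simulation held no structure between libraries. Pairs of libraries of one group were compared by a chi-square over genes with at least 20 counts summed over the pair: the lowest of 169 pairs had a chi-square of 5.09 per degree of freedom, so no library was taken as a repeat deposit of another. The p-values of the edgeR, DESeq2, limma voom and permutation tests take each library as a unit. Except where label series (given below) entered the test, they take libraries as independent. Label series accounted for 28.4% of the variance of log2 CPM. Fisher's exact test takes each gene as a unit, so its p-value does not measure the spread between libraries.

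Strand was examined with noncoding features that have at least 50% of their exonic bases inside exons of exactly one coding gene on the opposite strand, with at least 1 CPM on either (834 pairs). These measures, and the olfactory receptor level (log2 CPM of those genes summed, when used as a covariate), were chosen after the data were seen. Because the strand setting is unknown, the values of all genes are uncertain in what they count: with the opposite setting, a gene with no partner on the other strand would hold only reads from antisense transcripts, background or imperfect strand marking. For antisense features and genes that overlap another gene on the opposite strand, it is also uncertain which of the 2 a count came from. A count of 0 allows up to 3 counts; this floor covers counting error only, since reads without molecular identifiers are not independent molecules.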

Results

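RNA from coronary plaque of living patients was sequenced to ask how the plaque transcriptome of patients labelled ACS differs from that of patients labelled sCAD. The labels gave 14 ACS and 13 sCAD libraries, each made from about 5 ng of total RNA with the SMART-Seq Stranded Kit, a library chemistry that keeps the strand of the transcript. One library per patient was assumed, since the design text counts 14 and 13 patients and no label names a repeat. The deposited table held raw counts for 36601 gene identifiers. Total counts ran from 444584 to 1768282 per library, with a median of 950012, so that a gene at 0 counts could still hold 3 counts, or 2.98 CPM (counts scaled to a library total of 1000000) in ACS replicate 3. The number of genes with at least 1 count ran from 8278 in sCAD replicate 3 to 34358 in ACS replicate 8. The sample names were placed in 3 label series: one of 4 sCAD libraries alone, one of 6 ACS and 2 sCAD libraries, and one of 8 ACS and 7 sCAD libraries. The first holds the names with the prefix H. Names with the prefix HT were parted into the other 2 at the largest gap in their numbers. It is not known whether a series marks a batch.

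Some genes known to be abundant held few counts on their own gene and many on the annotated feature opposite it, and 4 were picked from the pairs with many counts on the feature. In CPM of the total count, UBB, which encodes ubiquitin, held 80.4 ± 84.7 CPM (SD, n = 27), while the antisense feature ENSG00000265401 inside it (GRCh38, chromosome 17, 16382152 to 16382669) held 10526 ± 11764 CPM. TPT1, the translationally controlled tumour protein gene, held 40.4 ± 31.9 CPM against 7494 ± 8613 CPM on the opposite feature ENSG00000273149. LYZ, the lysozyme gene of monocytes and macrophages, held 39.6 ± 43.8 CPM against 4238 ± 3892 CPM on ENSG00000257764. GAPDH held 15.7 ± 15.5 CPM against 544 ± 437 CPM on ENSG00000269968. For each of these 4 genes the opposite feature was higher in 27 of 27 libraries. Among 834 noncoding features with at least 50% of their exonic bases inside the exons of a single opposite coding gene, 662 (79.4%) held more counts per kb than that gene. Without that length scaling the feature was the higher in 244 of the 834 pairs (29.3%). Values given below for a gene are therefore TMM-scaled CPM of the counts assigned to that gene in the table. For a gene given by value, the gene or feature on the opposite strand is named where exons overlap, the one with the longest overlap where there are several.

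**Figure D1:**
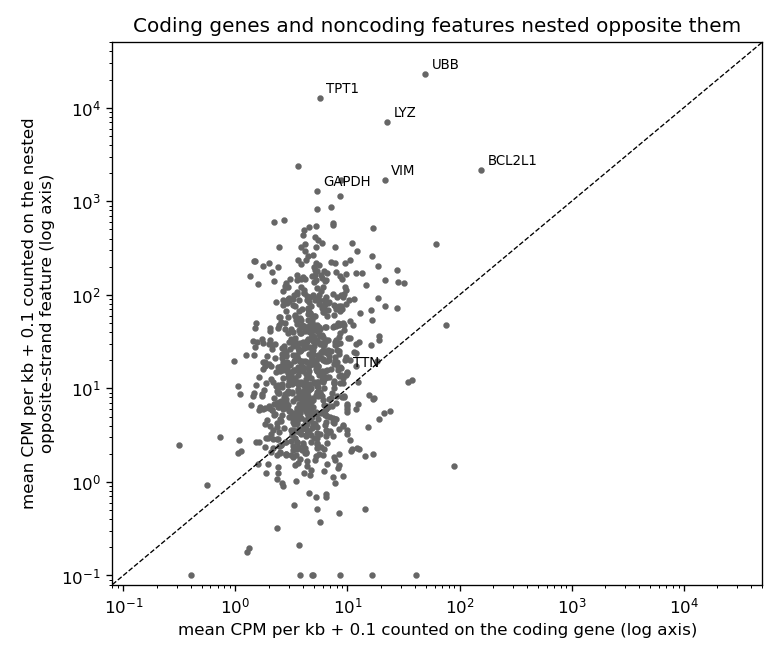
Mean CPM per kb of exon over 27 libraries, plus 0.1, on log axes: the coding gene on the x axis and the noncoding feature nested opposite it on the y axis, one point per pair (834 pairs), with a dashed line of equal values. In 662 pairs the feature lies above the line, and the pairs of UBB, TPT1, LYZ, VIM and GAPDH are among them.

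Genes of the olfactory receptor family also held counts. The 388 olfactory receptor genes, which encode odorant receptors of the nose, held a median of 0.905 times the counts per kb of the mean coding gene, from 0.156 in sCAD replicate 1 to 1.31 in ACS replicate 8. This ratio was 0.969 ± 0.267 in ACS (SD, n = 14) and 0.664 ± 0.399 in sCAD (n = 13), a difference of 0.304 (two-sided permutation test, p = 0.0283, adjusted p = 0.0283 over 3 measures chosen after the data were seen). The summed counts per kb on nested features relative to their coding genes were 11.4 ± 6.93 in ACS and 29.2 ± 21.3 in sCAD (adjusted p = 0.00832), and features annotated as antisense took 13.9 ± 3.99% of counts in ACS and 22.0 ± 9.18% in sCAD (adjusted p = 0.00832). Within the largest label series (8 ACS, 7 sCAD) the 3 differences had the same direction, with permutation p of 0.0951, 0.0717 and 0.0732, and adjusted p = 0.23 for each over 8 measures. The other series held 2 sCAD libraries or no ACS library and were not tested alone.

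**Figure D2:**
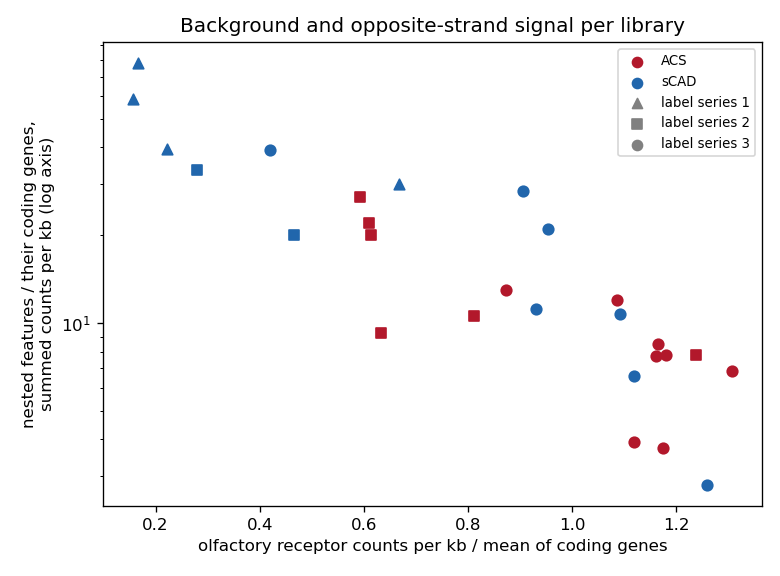
Each point is a library, coloured by group and shaped by label series. The x axis is the counts per kb of olfactory receptor genes relative to the mean coding gene, and the y axis (log) the summed counts per kb of nested features relative to their coding genes. Of the 4 sCAD libraries of label series 1, 3 lie at the upper left, below 0.25 on the x axis, and sCAD replicate 5 lies at 0.668. The ACS libraries lie above 0.59 on the x axis.

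The comparison of ACS with sCAD called 79 of 17828 tested genes (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 78 of them lower in ACS. Leaving out each library moved the count between 34 and 140, and with label series as a term it was 1. The count was 8 with RLE size factors, 20 with library size alone and 0 with the olfactory receptor level as a covariate (192 at an unadjusted p under 0.05). DESeq2 called 66 and limma voom 118. Calls mostly in 1 direction also arose with labels permuted within label series. In the permuted split with the most calls, 327 of 330 were lower in the group labelled ACS. Of 100 splits within label series, the real one included, 68 gave no call. Of 100 splits over all libraries, the real one included, 90 gave none. The adjusted p-values of the main test do not account for label series, so they may be too small. SLC4A1, which encodes the band 3 anion exchanger of red blood cells (ENSG00000004939, GRCh38 chromosome 17, 44248385 to 44268141), held 80.1 ± 45.6 CPM in ACS (SD, n = 14) and 1006 ± 1499 CPM in sCAD (n = 13), a log2 fold change of -3.65 (SE 0.62, adjusted p = 5.69e-05). ST13, an HSP70-interacting co-chaperone (ENSG00000100380, chromosome 22, 40824535 to 40857022), held 76.8 ± 44.5 CPM in ACS and 952 ± 1691 CPM in sCAD (log2 fold change -3.63, SE 0.62, adjusted p = 5.69e-05). Its medians were 71.3 CPM in ACS and 210 CPM in sCAD, with 5798 CPM in sCAD replicate 2. IRF1, a transcription factor of the interferon response (ENSG00000125347, chromosome 5, 132481609 to 132490798), held 72.2 ± 48.5 CPM and 761 ± 1265 CPM (log2 fold change -3.40, SE 0.61, adjusted p = 0.000132). IRF1 overlaps IRF1-AS1 on the opposite strand, which was also lower in ACS (log2 fold change -2.29, adjusted p = 0.0454).

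CYTH4, a cytohesin of blood cells, fell by 3.53 on the log2 scale (SE 0.61, adjusted p = 7.46e-05), and GIMAP4, a lymphocyte GTPase, fell by 3.45 (SE 0.66, adjusted p = 0.0012). GIMAP4 had medians of 16.3 CPM in ACS and 46.1 CPM in sCAD, with 2227 CPM in sCAD replicate 2. CDC34, a ubiquitin-conjugating enzyme, held 6.68 ± 8.12 CPM in ACS and 104 ± 131 CPM in sCAD (log2 fold change -3.93, adjusted p = 0.000132). The paraspeckle proteins NONO and SFPQ had log2 fold changes of -3.27 and -2.62 (adjusted p = 0.000142 and 0.0071), and the RNA-binding protein YBX1 one of -2.78 (adjusted p = 0.0086). EZR, which encodes ezrin, a linker of membrane and actin, had a log2 fold change of -2.60 (adjusted p = 0.0122) and overlaps EZR-AS1. UBXN6, a cofactor of the VCP ATPase, had one of -2.83 (adjusted p = 0.0023), and overlaps ENSG00000280239. UBXN6 also overlaps ENSG00000267769, which was called lower in ACS too (log2 fold change -3.27, adjusted p = 0.000338). Without sCAD replicate 2 the log2 fold changes of GIMAP4 (-2.04), SFPQ (-0.76) and EZR (-0.96) no longer passed. Without sCAD replicate 3 those of NONO (-1.94), YBX1 (-2.23) and EZR (-2.51) did not. TMC5, a transmembrane channel-like protein gene that overlaps ENSG00000260681 (log2 fold change -3.05, adjusted p = 0.00126), COG1, a Golgi tethering subunit (-2.60, adjusted p = 0.0125), and TSTD2 (-2.50, adjusted p = 0.0128) completed the 14 genes taken by the naming rule. The exons of COG1 overlap FAM104A and those of TSTD2 overlap TMOD1, which encodes the red-cell tropomodulin.

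Of the 77 called genes with a position in GENCODE 29, 54 (70.1%) overlapped exons of a coding gene on the opposite strand, against 26.1% of the other tested genes (Fisher's exact test, two-sided, p = 1.07e-15). Of the 77, 35 (45.5%) were annotated as antisense, against 11.5% of the other tested genes. Antisense features took a larger share of counts in sCAD over these same libraries, so these shares are not separate evidence of a group difference. Called and other genes were not matched for count level. Fisher's test takes genes as independent, although genes can vary together over libraries, so its p-value does not measure the spread between libraries. Among the genes opposite called features were PRDX2 and EPB41, which encode a peroxidase and a skeleton protein abundant in red cells, BCL2L1, an anti-apoptotic gene, and UBB. Their opposite features ENSG00000267062 (log2 fold change -2.55), TMEM200B (-2.57), ABALON (-2.55) and ENSG00000265401 (-2.57) were lower in ACS (edgeR, Benjamini-Hochberg adjusted p = 0.00898, 0.0128, 0.0193 and 0.0235). These 4 were chosen after their values were seen. The sCAD libraries varied widely at the called genes: SLC4A1 reached 3497 CPM in sCAD replicate 2 and 4596 CPM in sCAD replicate 3, and lay between 40.2 and 114 CPM in 6 other sCAD libraries. Without sCAD replicates 2 and 3, 10 genes were called, all lower in ACS. Within the largest label series edgeR called none (1680 genes had an unadjusted p under 0.05), and with label series as a term the only call was ST13.

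**Figure D3:**
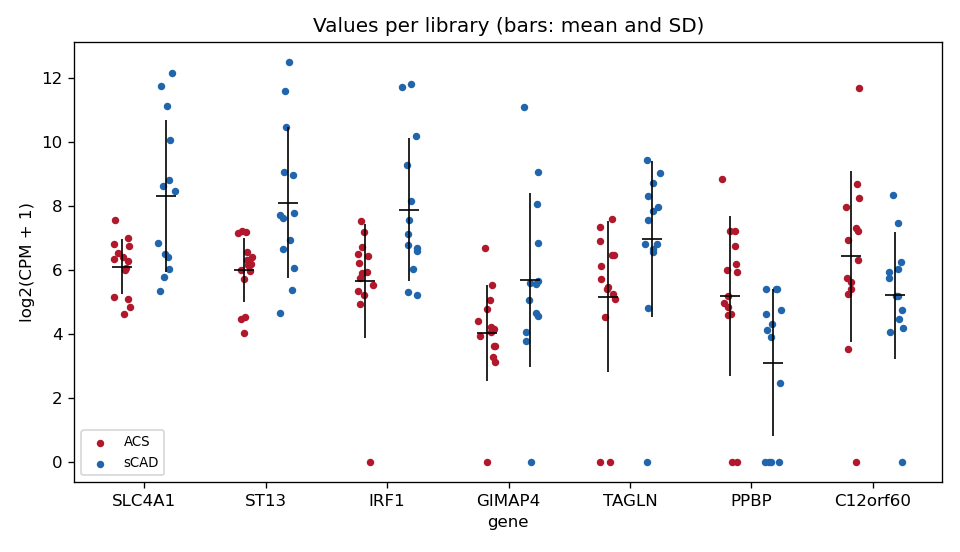
Values of 7 genes as log2(CPM + 1), one point per library (14 ACS, 13 sCAD), with horizontal marks at the mean and bars of 1 SD. For SLC4A1, ST13 and IRF1 the highest points are sCAD libraries, and the ACS values overlap with the lower sCAD values.

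Toward higher values in ACS, a single gene passed: ENSG00000286618, which GENCODE 29 does not list, at 62.4 ± 90.6 CPM in ACS and 9.19 ± 11.6 CPM in sCAD (log2 fold change 2.73, adjusted p = 0.0425); it falls outside the naming rule and was named because it stood alone. The 8 genes that filled the list did not pass. PPBP, the platelet basic protein gene (ENSG00000163736, chromosome 4, 73987038 to 73988197), held 86.4 ± 119 CPM in ACS and 17.6 ± 16.5 CPM in sCAD (log2 fold change 2.30, SE 0.65, adjusted p = 0.0757). PPBP held 0 CPM in sCAD replicates 1, 2, 3 and 6 and in ACS replicates 3 and 4. These libraries had the fewest detected genes of their groups. The ACS mean of PPBP included 465 CPM in ACS replicate 12. C12orf60 (chromosome 12, 14803572 to 14906586) had a log2 fold change of 2.34 (adjusted p = 0.128), and its exons overlap MGP, the matrix Gla protein gene; its ACS mean of 355 CPM included 3292 CPM in ACS replicate 10. OR8S1, an olfactory receptor gene, SPEM3, RASSF6, GIPR, the receptor of a gut incretin, B4GALNT1, a ganglioside synthase whose exons overlap SLC26A10P, and RANBP6 had log2 fold changes between 1.99 (B4GALNT1) and 2.39 (SPEM3), with adjusted p from 0.188 (OR8S1) to 0.337 (RANBP6).

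With labels permuted over all libraries, none of the 58 tested gene lists passed (two-sided permutation test of mean log2 CPM, Benjamini-Hochberg); the smallest p was 0.0532 and every adjusted p was 0.503 or more. With labels permuted within label series, the fibrillar collagen and modulated smooth muscle lists passed, both higher in ACS (adjusted p = 0.0441 for each), and in camera with an estimated correlation neither did (adjusted p = 0.968 for each). Scores of 46 of the 58 lists were higher in ACS without passing, among them the epithelial (0.73, SE 0.47), neural (0.64, SE 0.46), cardiomyocyte (0.60, SE 0.42) and adipocyte (0.58, SE 0.38) lists, so a positive difference was not particular to matrix genes. All 20 measured members of the fibrillar collagen and matrix list had a positive log2 fold change and none passed, among them POSTN, a matrix protein (1.64, adjusted p = 0.572), FN1, fibronectin (0.99, adjusted p = 0.811), and COL3A1 (0.72, adjusted p = 0.941). The score of that list was higher by 0.91 in ACS (SE 0.45, permutation p = 0.0532), with adjusted p = 0.0901 in camera with a preset correlation. It lay between 2.03 and 3.24 in sCAD replicates 1, 2, 3 and 6, against a mean of 4.45 over the 13 sCAD libraries; these 4 had the fewest detected genes among the sCAD libraries (8278 to 16196). Without sCAD replicates 2 and 3 the list had an adjusted p of 0.925. The modulated smooth muscle list differed by 0.90 (SE 0.47, adjusted p = 0.503) and the endothelial list by 0.73 (SE 0.39, adjusted p = 0.503), with 10 of 11 and 13 of 15 members above 0. The erythroid list differed by -0.60 (SE 0.48, adjusted p = 0.503), with 7 of 11 members below 0. SLC4A1 was called, and the haemoglobin genes HBA2 (log2 fold change -2.25, adjusted p = 0.825), HBB (-1.12, adjusted p = 0.888), HBA1 (-0.67, adjusted p = 0.948) and HBD (0.94, adjusted p = 0.941) were not. In the ribosomal protein list 14 of 20 members lay below 0 (score difference -0.34, SE 0.33, adjusted p = 0.577). Heat shock, interferon-gamma and autophagy lists each held 1 called gene, lower in ACS: HSP90AB1 (-2.41, adjusted p = 0.0184), IRF1, and OPTN, an autophagy receptor whose exons overlap CCDC3 (-2.19, adjusted p = 0.0371). The neutrophil, platelet and classical monocyte scores differed by 0.17, 0.13 and 0.00 (SE 0.29, 0.41 and 0.31).

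Of the 36 genes of the fixed panel, 23 passed the count filter and none was called over all genes; adjusted over the list alone, PPBP (adjusted p = 0.00977) and TAGLN (adjusted p = 0.0168) passed. TAGLN, the transgelin gene of contractile smooth muscle, held 68.0 ± 57.8 CPM in ACS and 237 ± 206 CPM in sCAD (log2 fold change -1.80, SE 0.56, edgeR adjusted p = 0.151 over all genes), and its exons overlap PCSK7. The smooth muscle genes MYH11 and ACTA2 had log2 fold changes of -0.88 (SE 0.56) and -1.04 (SE 0.61), which did not pass, and overlap NDE1 and ACTA2-AS1. The contractile smooth muscle list, which holds TAGLN, MYH11 and ACTA2, showed no such direction. Of its 16 measured members 8 lay above and 8 below 0. Its score differed by 0.03 (SE 0.32, permutation test, adjusted p = 0.965). The inflammatory genes did not pass either: IL1B had a log2 fold change of 1.02 (SE 0.73), MMP9, a matrix protease that overlaps SLC12A5-AS1, -0.95 (SE 0.62), TNF -0.20 (SE 0.75) and NLRP3 0.29 (SE 0.69). The macrophage genes CD68, which overlaps ENSG00000233223, and CD163 had values of -0.10 (SE 0.71) and 0.40 (SE 0.57), and the endothelial gene VWF 0.75 (SE 0.56). IL6, CXCL8, CCL18, MMP1, MMP12, SPP1, LGALS3, APOE, TREM2, FABP4, GZMB, S100A9 and F3 did not pass the count filter and were not tested.

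The group accounted for 6.68% of the variance of log2 CPM (permutation p = 0.0751), against a mean of 3.84% for permuted labels, and the 3 label series accounted for 28.4% (permutation p = 0.001, the smallest the 999 permutations could give). For total count, genes detected, the share of the 100 most abundant genes, and haemoglobin and mitochondrial shares, no group difference passed (permutation test, adjusted p from 0.286 to 0.743). The 100 most abundant genes took 20.1 ± 10.8% of counts in ACS and 28.0 ± 13.8% in sCAD. Mitochondrially encoded genes took 9.02 ± 7.62% of counts in ACS and 5.13 ± 4.24% in sCAD.

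**Figure D4:**
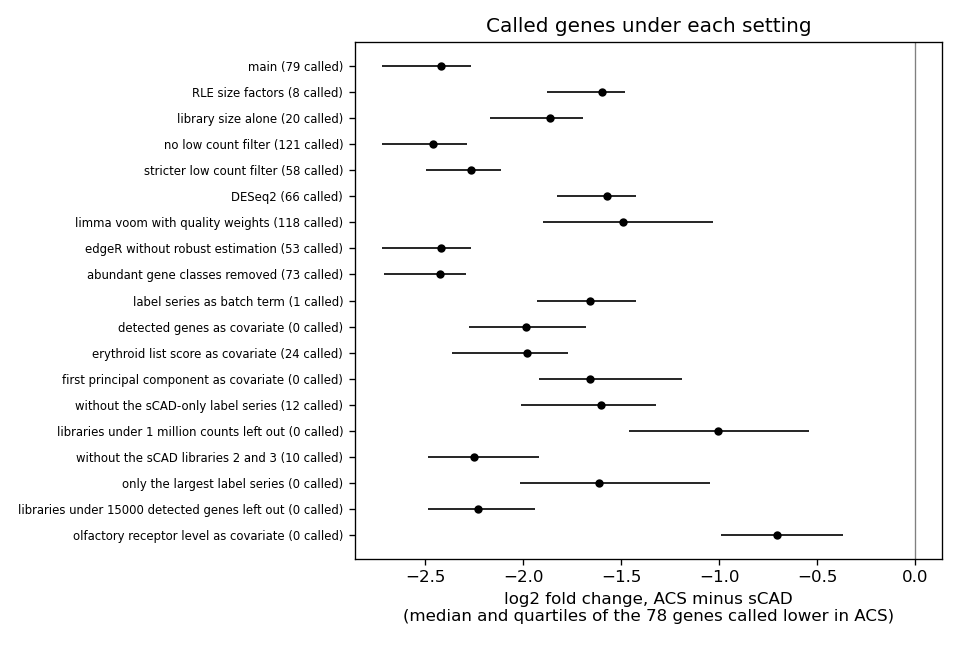
Median log2 fold change (points) with quartiles (bars) of the 78 genes called lower in ACS, under each setting of the analysis, with the number of genes called in brackets. The median was -2.42 in the main test and -0.70 with the olfactory receptor level as a covariate.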

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

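The splits within label series and the settings without sCAD replicates 2 and 3, within the largest label series, with libraries under 15000 detected genes left out and with the olfactory receptor level as a covariate were chosen after the data were seen. The count of 79 genes (1 higher and 78 lower in ACS) became 8 with RLE size factors and 20 with library size alone. Without a filter it was 121 (27 higher and 94 lower). With label series as a term it was 1, and with the erythroid score as a covariate 24. The count was 12 without the label series that held sCAD alone, and 10 without sCAD replicates 2 and 3. It was 0 with detected genes, the first principal component or the olfactory receptor level as a covariate, with libraries under 1000000 counts or under 15000 detected genes left out, and within the largest label series (edgeR; 1381, 1003, 192, 96, 1468 and 1680 genes at an unadjusted p under 0.05). Fewer samples enter the last 3 of these; otherwise the cause was not tested. DESeq2 called 8 higher and 58 lower, 44 of them shared with the 78, and limma voom 9 higher and 109 lower, 21 of them shared. Leaving out each library gave 34 to 140 calls. Counts beyond 1.5 times followed from leaving out ACS replicates 2 (46), 3 (41), 4 (37), 6 (137), 7 (37), 8 (35), 9 (38), 10 (42), 11 (47), 13 (41) and 14 (39), and sCAD replicates 3 (34), 4 (38), 8 (140) and 10 (133).

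With libraries under 1000000 counts left out, GIMAP4 (0.39), SFPQ (0.90) and YBX1 (0.0697) had positive log2 fold changes. The fixed panel gave 1 call with limma voom (TAGLN) and 1 with the erythroid score as a covariate (PPBP), and 0 to 1 on leaving out each library (PPBP without sCAD replicate 7 or 8). The lists gave 2 calls with labels permuted within label series, fibrillar collagen and modulated smooth muscle (adjusted p = 0.0441 for both), and 0 otherwise, including each library left out. The share of variance between ACS and sCAD lay between 5.33% and 8.18% on leaving out each library (p from 0.0395 to 0.168); the share of variance between ACS and sCAD passed without ACS replicate 4 (8.08%) or sCAD replicates 8 (8.18%) or 10 (8.01%). The 5 planned library measures gave 0 calls in every setting run. Values past the threshold in neither setting changed direction in 221 of the list comparisons (by the tool's own direction in camera and fry) and 77 of those of single genes. The count filter left 13 panel genes untested, and whether depth or strand counting lowered them was not tested. No paired analysis was possible because the replicate numbers only follow the order of the samples.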

Other observations

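All tests in this part were chosen after the main result was seen; for the olfactory receptor covariate and the unrestricted splits of the libraries, the bounds were written before their own results were seen. When nested features were read as the signal of the coding gene opposite them, 662 features with more counts per kb than that gene were available, and 335 passed the filter. Normalised among themselves, none differed between ACS and sCAD (edgeR, smallest adjusted p = 0.315, 24 at an unadjusted p under 0.05), and none did within the largest label series (smallest adjusted p = 0.187, 30 at an unadjusted p under 0.05). This scaling removes a rise shared by the features: scaled over all genes, a number of such features were called lower in ACS. Among them were those opposite BCL2L1, UBB, EEF1D and TEX9, with log2 fold changes of -2.55, -2.57, -2.29 and -3.10. The 5 smallest p fell on the features opposite BCL2L1, an anti-apoptotic gene (log2 fold change -1.15, SE 0.33), TEX9 (-1.76, SE 0.57), UBB (-1.07, SE 0.36), EEF1D, an elongation factor subunit (-0.87, SE 0.30), and MBP, the myelin basic protein gene (2.36, SE 0.80). The feature opposite THBS1, thrombospondin, had a value of 1.57 (SE 0.62) and that opposite TPT1 -0.81 (SE 0.31). Those opposite LYZ (-0.25, SE 0.34), VIM (0.00, SE 0.33), GAPDH (0.22, SE 0.29) and TPM1, a tropomyosin gene (0.64, SE 0.34), had an adjusted p of 0.803 or more.

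Features opposite coding genes held more counts per kb than the genes in most pairs. True antisense transcription counted on the correct strand would leave lists of abundant genes high among random lists of coding genes. By median CPM the ribosomal protein list stood at the 71.3 percentile and the nuclear oxidative phosphorylation list at 0.95. The glycolysis list (35.1 CPM) lay above the 95th percentile (29.6 CPM). The random lists were not matched for gene length, and counts of coding genes rose with exonic length (Spearman correlation 0.25 to 0.74 by library). These lists therefore cannot decide for or against true antisense transcription. Counting that ignored strand would leave a fully nested feature with no more counts than its gene. Of 337 such features, 96 held more, among them those opposite UBB, TPT1, LYZ and GAPDH, each higher in 27 of 27 libraries. If 1 setting was used for the whole table, this argues against counting that ignored strand. The pairs in which the gene held more do not decide the question. By counts the feature was the higher in 29.3% of all pairs, and per kb in 79.4%. Of the 78 pairs whose feature held at least 100 CPM, 74 had the feature above the gene by counts. Those pairs were chosen by the level of the feature itself. A candidate explanation that stays open is counting with the setting opposite to that of the stranded kit; the summed counts per kb of nested features exceeded those of the genes in each of 27 libraries, by 2.79 to 77.6 times, although the share of single pairs ran from 22.4% to 76.3%.

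Olfactory receptor genes held at least 0.5 times the counts per kb of the mean coding gene in 21 of 27 libraries. A background of reads that do not come from expressed genes, such as genomic DNA, may give such counts. If coding genes were also read on the opposite strand, their counts would be low and the ratio would rise, so both explanations can hold at once, and the size of a background in the total is not given by this ratio. No biological explanation was tested for this pattern. For the one before, only true antisense transcription was examined, and it was not decided.

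The 78 genes called lower in ACS had a median log2 fold change of -2.42 (quartiles -2.72 and -2.27). Of 100 splits of the 27 libraries, 4 gave 79 calls or more, the real one included, with 92 the highest of the others. Of 100 splits within label series, 4 did, the real one included, with 330 the highest of the others. Each share lay close to 0.05, and 100 splits do not fix it closely enough to exclude chance. In the split with 330 calls, all 4 libraries of the sCAD-only label series stood in one group. They did so too in 2 of the 3 other unrestricted splits with as many calls. However, every split within label series keeps these 4 libraries together, and 68 of the 100 gave no call. Of the 100 unrestricted splits 90 gave none, so calls came more often where these 4 libraries were kept together. A structure of the samples that involves these 4 libraries is possible, but their place does not alone set the count. The median was -2.25 without sCAD replicates 2 and 3, where 10 genes were called, and -1.61 (quartiles -2.02 and -1.05) within the largest label series, where edgeR called none (1680 at an unadjusted p under 0.05). Since the genes were chosen on these libraries, sets of 78 genes were chosen in the same way from permuted labels. With the other 25 labels permuted, 1 of 100 splits, the real one, gave as low a median (lowest other -2.19). By this small margin, the splits argue against sCAD replicates 2 and 3 as the whole cause. They mixed the label series, so they do not tell a group difference from one between label series. With labels permuted within series, 6 of 100 splits, the real one included, gave as low a median (lowest other -2.15). Label series therefore stays open. With the olfactory receptor level as a covariate the median was -0.70 (quartiles -0.99 and -0.37) and no gene was called, a value between the bounds set in advance, so a share of background counts and a difference between ACS and sCAD were not separated: the olfactory receptor ratio itself differed between the groups.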
